A study of Mus musculus with 6 samples.

How the data were processed

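RNA from 6 mpkCCD clones, 3 control and 3 PKA dKO, was depleted of ribosomal RNA from 262 ng of total RNA and made into stranded libraries with random priming, per the labels' protocols, and sequenced on an Illumina instrument. The submitters' processing notes name STAR 2.5.2a, SAMtools, HOMER 4.8, edgeR and the build GRCm38.p5, without saying what each was used for. Which reads were counted, whether strand was used and how reads mapping to several places were treated is not given in the sources used here, so reads of overlapping genes, antisense pairs and near-identical paralogs cannot be told apart. Small and structural RNAs stayed in the libraries: Rn7sk, Rpph1, Rmrp and Malat1 took 7.39% to 9.67% of the reads in the table.

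The deposited read table gives, for 20896 transcripts with 1 per gene, a read column and an FPKM column per library. The header calls the first read counts, but the values are not whole and all 6 libraries sum to the same total, so they are a signal in which the authors scaled each library's reads to a common total. Within a library every value is a whole multiple of 1 step (0.427 to 0.635 scaled reads), and dividing by the step gave whole reads for 100% of values at a tolerance of 0.01 scaled reads. The recovered totals, 28596444 to 42515838 reads, are the depth behind the values. The deposited FPKM values imply larger library totals, of which the reads in the table are 31.7% to 48.7%; what else the authors counted in those totals is not given in the sources used here. The authors' deposited comparison table holds log2 fold changes, mean log2 CPM, p-values and false discovery rates from edgeR, per the file headers. The lowest mean of recovered reads among its transcripts was 105. Transcript length, in bases, is listed with each transcript. Of the transcript identifiers, 20811 (99.6%) were found in the GENCODE M21 annotation of GRCm38 and 17097 had the same start and end; coordinates printed are those of the deposited table, and exon counts come from M21. The table holds 25 gene symbols that a spreadsheet had turned into dates; they were tested under their transcript identifiers and none is named here.

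An edgeR quasi-likelihood test on counts had been fixed as the main test before the data were examined. Because the read columns proved to be scaled reads, the main test was limma-trend (limma 3.58.1, R 4.3.3) on log2 of scaled reads adjusted with TMM factors (edgeR 4.0.16; 0.909 to 1.07), with a pseudocount of 1 scaled read, which is about 0.055 CPM. Fold changes are on this log2 scale and understate changes of low genes. Transcripts entered the test when filterByExpr kept them by group on recovered reads (minimum 10 reads, minimum total 15), leaving 16683 and excluding 4213. The fit used all 6 libraries with group as the only term, and p-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. The edgeR quasi-likelihood test on the recovered reads, run as an added alternative, called 28 genes, 25 of them shared with the main test. CPM values were computed from recovered reads with TMM-adjusted library sizes and are given as mean ± SD over 3 clones; intervals are 95% intervals of the fitted fold change. Each clone is a separate line with 1 library. The p-values therefore weigh the group difference against the spread between these libraries, moderated across genes. That spread includes clonal differences other than the knockout, and it cannot be told apart from library and culture differences.

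On simulated counts drawn for this comparison over 15972 genes, limma recovered 5 of 67 genes changed 1.5-fold (7.46%), 36 of 67 changed 2-fold (53.7%) and 59 of 66 changed 4-fold (89.4%), with 5 false genes among 107 calls. These changed genes were drawn only from genes with a mean above 1 CPM, so recovery among lower genes was not checked. A planted list passed camera and 0 of 19 unchanged lists did. The simulated genes were drawn independently of one another, whereas the estimated correlation reached 0.79 in the list of mitotic genes. The simulation therefore could not check camera at the preset correlation on lists whose genes vary together. Changes of 1.5-fold were thus mostly missed in this simulation.

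The genes named were chosen by a rule fixed before the data were examined: Prkaca and Prkacb; Aqp2, Aqp3, Avpr2 and the Scnn1a, Scnn1b and Scnn1g genes; up to 12 genes with the highest and 12 with the lowest fold change among those past the threshold whose groups do not overlap and whose higher mean is at least 2 CPM, leaving out predicted or clone-named models; the 4 members of each list with the lowest p; and the 5 genes past the threshold with the highest mean CPM. AU021092, Tmem45b, Dock5, Mettl7a1, Nadk2 and the genes of the 2 lists made later were named after their values were seen. The 26 lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, and members were also adjusted over the list alone; 25 had members tested.

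Alternatives fixed in advance were RLE and upper-quartile factors, no filter and a filter of 1 CPM, DESeq2 1.42.0, limma-voom and edgeR's exact test on recovered reads, FPKM with pseudocounts of 1 and 0.1, the clone number as a block, a threshold of 0.01, a minimum absolute log2 fold change of 1, and leaving out each library. Added after the data were seen were the quasi-likelihood test, a term for the 2 libraries that stood apart, the share of gene reads as a covariate, the other 4 libraries alone, pseudocounts of 0.25 and 4, removal of each library's chromosome medians, and the exact test on the transcripts of the authors' deposited table. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for reading the files and for plots.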

Results

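Total RNA was sequenced from clonal lines of mpkCCD, a mouse cell line derived from the kidney cortical collecting duct, where vasopressin controls water uptake. There were 6 libraries, from 3 control clones and 3 clones labelled as double knockouts of protein kinase A (PKA dKO), with 1 library per clone. PKA is the kinase that cyclic AMP activates when vasopressin binds its V2 receptor. All 6 clones were kept on permeable supports for 4 days with 2% serum and supplements, and then exposed for 3 days to dDAVP, a vasopressin analog selective for the V2 receptor, at 0.1 nM in medium without serum or added hormones. The comparison therefore asks how expression under dDAVP differs between control clones and clones with the PKA dKO label, and the series title states the aim of finding the PKA-dependent network. No library without dDAVP was analysed here, so the response to dDAVP itself was not measured.

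Recovered reads assigned to genes numbered 39780099, 28596444 and 42515838 in control clones 1, 2 and 3, and 38760162, 30541578 and 37854925 in dKO clones 1, 2 and 3. The table listed 20896 transcripts, 1 per gene, of which 16683 passed the filter on low reads and were tested. Within a group, the libraries differed far beyond sampling noise, with a chi-square per degree of freedom of 19.6 to 69.5, so no library was counted as a repeat of another. Control clone 1 and dKO clone 3 stood apart from the other 4 libraries. They had no read on 2443 and 2363 transcripts, against 863 to 1045 in the other 4. At least 1 read was found on 50.8% and 51.0% of the 1351 olfactory and vomeronasal receptor transcripts, genes of sensory neurons, against 81.9% to 87.4% in the other 4 libraries. The first principal component, with 68.1% of the variance, had these 2 libraries at -91.7 and -76.8 and the other 4 between 20.9 and 74.2. Because each group held 1 of these 2 libraries, the comparison was also made within the other 4 libraries and with this split as a term, both chosen after the data were seen.

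**Figure D1:**
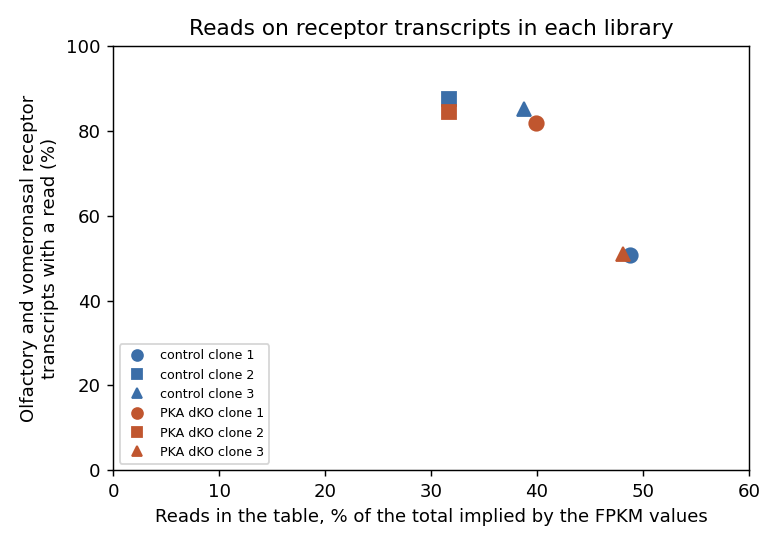
Share of olfactory and vomeronasal receptor transcripts with at least 1 read (vertical axis, %) against reads in the table as a percentage of the library total implied by the FPKM values (horizontal axis, %), 1 point per library. Control clone 1 and dKO clone 3 lie at 50.8% and 51.0% of receptor transcripts and the other 4 libraries between 81.9% and 87.4%.

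The labels do not name the edited genes. They were taken to be Prkaca and Prkacb, which encode the PKA catalytic subunits alpha and beta. Prkaca (ENSMUSG00000005469.10; transcript ENSMUST00000005606.6, GRCm38 chromosome 8, 83972978 to 83996445, plus strand, a protein-coding gene with 10 exons in its annotated transcript) fell in the dKO clones. Its level was 99.8 ± 29.6 CPM (SD, n = 3) in control clones and 7.53 ± 0.92 CPM in dKO clones, 12.9-fold lower with a 95% interval of 9.43 to 17.6. The log2 fold change was -3.69 (SE 0.20; limma adjusted p = 1.67e-05). Single clones had 133, 75.9 and 90.6 CPM in the control group and 6.65, 8.49 and 7.44 CPM in the dKO group. Prkaca was thus lower in each dKO library than in any control library. Because the labels do not name this gene, its fall goes with the assumption made here without identifying the edited genes. Between 265 and 268 Prkaca reads remained in each dKO library.

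Prkacb (ENSMUSG00000005034.15; transcript ENSMUST00000102515.9, chromosome 3, 146729574 to 146812960, minus strand, 10 exons) had 121 ± 14.6 CPM in control clones and 103 ± 3.43 CPM in dKO clones (n = 3 each). Its log2 fold change of -0.23 (SE 0.13) did not pass the test (limma adjusted p = 0.933), although the 3 dKO values, 99.1, 105 and 105 CPM, lay below the control values of 138, 109 and 117 CPM. Where the edits lie in the 2 genes is not given in the sources used here, and reads outside an edited site do not show whether protein is made, so Prkacb mRNA does not check the label. Of the 10 genes of PKA subunits and inhibitors tested, Prkaca alone passed, over all genes and adjusted over the list alone. The regulatory subunit gene Prkar1a had a log2 fold change of 0.15 and the inhibitor gene Pkia 0.36, neither past the threshold. The list as a whole did not pass camera (adjusted p = 0.629).

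**Figure D2:**
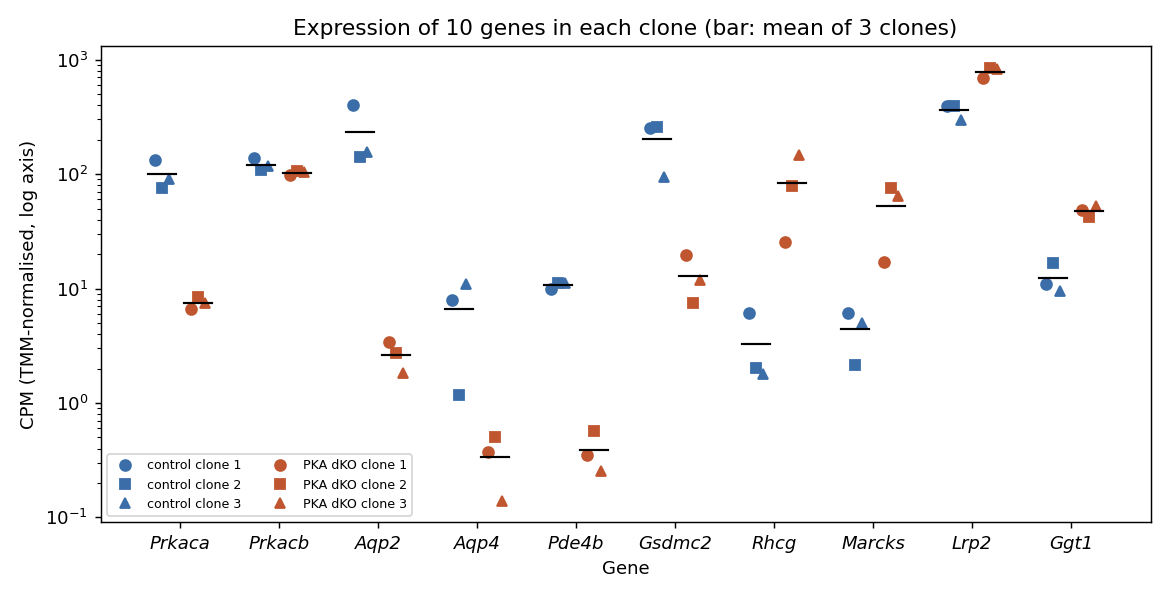
TMM-normalised CPM (log axis) of 10 genes in each of the 6 clones, with 1 point per clone and a bar at the mean of 3 clones. Prkaca lies at 6.65 to 8.49 CPM in the dKO clones and 75.9 to 133 CPM in the control clones, whereas Prkacb lies between 99.1 and 138 CPM in all 6.

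Across all genes tested, 28 changed between dKO and control clones (limma-trend, Benjamini-Hochberg adjusted p under 0.05): 9 were higher and 19 lower in dKO clones. An unadjusted p under 0.05 was found for 1045 genes. In all 28 the values of the 3 dKO clones lay outside those of the 3 control clones, against 10.8% of all genes tested and 10% by chance. Selection by a small p from 3 clones per group nearly forces this, so it gives no separate support. Within the 4 libraries other than control clone 1 and dKO clone 3, 525 genes passed (270 higher, 255 lower), among them all 28, and with the split of libraries as a term 71 passed (20 higher, 51 lower), again with all 28. The term leaves the fold changes as they were, because each group held 1 of the libraries that stood apart. The 4 libraries also took part in selecting the 28, so keeping all 28 is no independent check. The count depended on single libraries: it was 146 without control clone 1, 47 without dKO clone 3, 13 without dKO clone 1 and 11 without dKO clone 2, and 11 genes stayed past the threshold in all 6 fits that left out 1 library, namely Prkaca, Aqp2, Pde4b, Gsdmc2, Gsdmc4, Ggt1, Rhcg, Zhx2, Hid1, Upk1a and AU021092. Without dKO clone 2 the calls of Marcks, Lrp2, Bnip3, Inmt, Tmprss4, Upk3b, Pvrl3, Egln3, Nrep, Itgb6, Baiap2l2, Oxr1 and Cd55 were lost, as were those of Tmem45b, Dock5, Mettl7a1 and Nadk2, named after their values were seen. Without dKO clone 1 the same genes were lost except Marcks and Pvrl3.

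**Figure D3:**
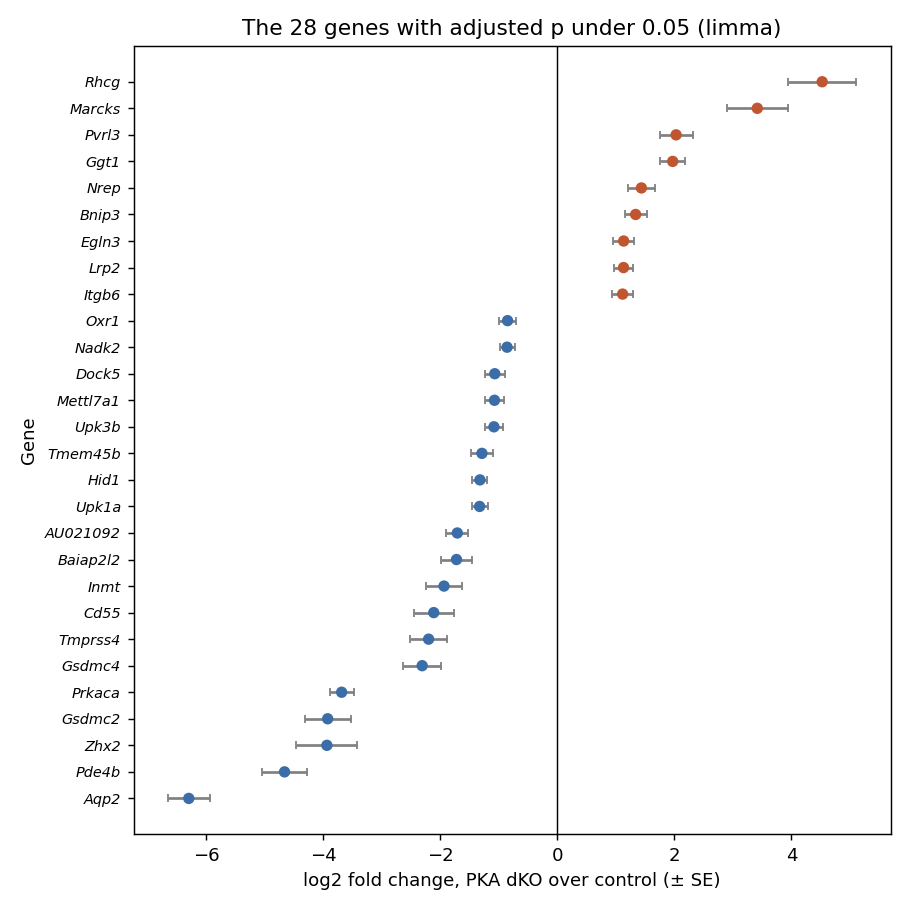
Log2 fold change of PKA dKO over control clones (horizontal axis, point) with its standard error (bar) for each of the 28 genes with a limma adjusted p under 0.05, n = 3 clones per group. The values run from -6.30 for Aqp2 to 4.52 for Rhcg, with 19 genes lower and 9 higher in dKO clones.

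Aqp2, the water channel that vasopressin controls in the principal cells of the collecting duct, was the gene with the lowest fold change of the 28. It fell from 232 ± 145 CPM in control clones to 2.65 ± 0.78 CPM in dKO clones (n = 3 each), 78.7-fold lower with a 95% interval of 45.8 to 135, and a log2 fold change of -6.30 (SE 0.35; limma adjusted p = 1.67e-05). The gene (ENSMUSG00000023013.5; chromosome 15, 99579056 to 99584545, plus strand, 4 exons) had 4272 to 14417 reads in the control libraries and 65 to 136 in the dKO libraries. Control values were 399, 140 and 157 CPM, so the control clones themselves spread widely. The log2 fold change of Aqp2 was -5.58 within the 4 libraries and -7.73 in dKO clone 3 against control clone 1, so its size depends on the libraries used. Chromosome 15 held 8 of the 28 genes, including Aqp2, all lower in dKO clones.

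The other genes tied to vasopressin action that were fixed for reporting did not pass. Avpr2, the V2 receptor gene, had 58.6 ± 5.78 CPM in control and 46.9 ± 3.03 CPM in dKO clones, a log2 fold change of -0.32 (SE 0.13; limma adjusted p = 0.688). The water channel gene Aqp3 was low in both groups, at 1.48 ± 0.11 and 1.69 ± 0.15 CPM, with a log2 fold change of 0.18 (SE 0.38). The subunits of the epithelial sodium channel had log2 fold changes of 0.02 for Scnn1a (SE 0.16; 329 ± 64.1 CPM in control clones), 0.01 for Scnn1b (SE 0.43; 2.16 ± 0.27 CPM) and 0.14 for Scnn1g (SE 0.21; 34.9 ± 11.4 CPM), and the sign of each turned in at least 1 alternative setting. Among 21 principal-cell genes, Aqp2 passed over all genes, and Aqp2 and Aqp4 passed adjusted over the list alone. Aqp4, the basolateral water channel, had 6.66 ± 4.96 CPM in control and 0.34 ± 0.19 CPM in dKO clones, a log2 fold change of -3.72 (SE 0.78, limma adjusted p = 0.130 over all genes). Its control values were 7.94, 1.18 and 10.9 CPM, so control clone 2 lay near the dKO values of 0.37, 0.51 and 0.14 CPM. Principal-cell members also went the other way without passing, such as the transcription factor gene Tfcp2l1 at 0.53 (529 ± 118 to 751 ± 22.1 CPM), while the mineralocorticoid receptor gene Nr3c2 stood at -0.69. Positive fold changes were found for 13 members and negative ones for 8. At an unadjusted p under 0.05, 4 members were lower and 1 higher, and DESeq2 called 2 lower and 0 higher. The list's median was 0.07, its mean -0.41, and camera found no difference from other genes (adjusted p = 0.388).

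Pde4b, a phosphodiesterase that degrades cyclic AMP, fell from 10.8 ± 0.69 to 0.39 ± 0.16 CPM, 25.3-fold (log2 fold change -4.66, SE 0.38; limma adjusted p = 5.61e-04). The gasdermin C family genes Gsdmc2 and Gsdmc4, which encode relatives of pore-forming proteins, fell from 201 ± 92.4 to 13.0 ± 6.08 CPM and from 34.6 ± 8.38 to 7.35 ± 3.54 CPM. They are neighbouring paralogs on chromosome 15, and how reads shared between such copies were assigned is not given in the sources used here, so their separate values are uncertain. Zhx2, a transcriptional repressor gene also on chromosome 15, fell from 12.8 ± 1.53 to 0.97 ± 0.62 CPM (log2 fold change -3.94; -3.12 within the 4 libraries and -5.57 in dKO clone 3 against control clone 1). The uroplakin genes Upk1a and Upk3b, whose products line the apical membrane of urothelium, fell from 120 ± 11.7 to 47.7 ± 5.65 CPM and from 190 ± 32.2 to 89.1 ± 9.98 CPM. Hid1, which acts in the formation of secretory granules, fell from 84.0 ± 6.73 to 33.5 ± 2.26 CPM.

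Further lower genes were the membrane serine protease gene Tmprss4 (log2 fold change -2.20), Cd55, which limits complement on the cell surface (-2.11), the methyltransferase gene Inmt (-1.94), Baiap2l2 (-1.72) and Oxr1, named for oxidation resistance (-0.85). Dock5 lies on chromosome 14 and was lower by a log2 fold change of -1.07 (-0.79 within the 4 libraries and -1.61 in dKO clone 3 against control clone 1); it stayed past the threshold when each library's chromosome medians were removed (-0.85, adjusted p = 0.0137). Inmt lies on chromosome 6, whose genes had a median deviation of -0.38 in dKO clone 3. Inmt had 27.4, 16.9 and 45.4 CPM in dKO clones 1, 2 and 3. Its lower level thus did not rest on dKO clone 3, where it was highest of the dKO clones. The call of Inmt was lost when each library's chromosome medians were removed (limma adjusted p = 0.126), as were those of Oxr1 (0.0621) and Egln3 (0.0999). The log2 fold change of Inmt was -1.94 (SE 0.30) before this step and -1.78 (SE 0.37) after it, that of Egln3 1.13 (SE 0.18) and 1.05 (SE 0.20), and that of Oxr1 -0.85 (SE 0.14) and -0.73 (SE 0.13). The difference was smaller for each of them. For Inmt and Egln3 the error was also larger, and which of the 2 ended those calls was not tested. For Oxr1 the error was smaller, so a larger error did not end its call. Over 26 settings the adjusted p of these genes ran from 7.10e-11 to 0.126 for Inmt, 1.16e-06 to 0.557 for Oxr1 and 1.21e-06 to 0.177 for Egln3. The log2 fold changes of Inmt and Tmprss4 were -2.47 and -2.62 within the 4 libraries and -0.85 and -1.34 in dKO clone 3 against control clone 1.

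Rhcg, an ammonia transporter of the collecting duct, had the highest fold change. It rose from 3.31 ± 2.41 to 83.3 ± 60.8 CPM, 23.0-fold with a 95% interval of 9.50 to 55.8 (log2 fold change 4.52, SE 0.58; limma adjusted p = 0.0156). The dKO clones differed widely among themselves, at 25.3, 78.0 and 147 CPM, all above the control values of 6.09, 2.03 and 1.80 CPM. Marcks, a membrane and actin-binding substrate of protein kinase C, rose from 4.42 ± 2.07 to 52.3 ± 31.1 CPM (log2 fold change 3.42, SE 0.52, limma adjusted p = 0.0359). Its dKO values were 17.1, 76.0 and 63.7 CPM, so the size of the rise depends on the clone. The adhesion gene Pvrl3 (nectin 3) rose 4.08-fold, from 4.48 ± 1.59 CPM in control clones, and Ggt1, which cleaves extracellular glutathione, rose from 12.4 ± 3.87 to 47.7 ± 5.34 CPM. Lrp2, the endocytic receptor megalin, was the most abundant of the genes that rose, from 361 ± 53.5 to 787 ± 87.5 CPM. Nrep (log2 fold change 1.44; 1.84 within the 4 libraries and 0.65 in dKO clone 3 against control clone 1), Bnip3 (1.34), Egln3 (1.13) and Itgb6, an integrin subunit gene (1.11), completed the 9 higher genes. Bnip3 and Egln3 stood at 1.61 and 1.39 within the 4 libraries and at 0.80 and 0.63 in dKO clone 3 against control clone 1. The calls of Rhcg and Marcks did not hold with limma-voom, although their signs did.

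Gene lists fixed before the data were examined were tested with camera against all other genes. Of 25 lists with members tested, 7 passed at the preset correlation of 0.01, and none did with an estimated correlation or with fry, which asks whether the genes of a list differ between the groups without comparing them with other genes. Genes of glycolysis and the hypoxia response rose as a list (median log2 fold change 0.45; camera adjusted p = 1.93e-11, adjusted p = 0.268 with an estimated correlation). Of its 22 members 20 had a positive fold change, 2 passed over all genes and 11 adjusted over the list alone; 12 had an unadjusted p under 0.05, all higher, and the quasi-likelihood test called 2 and DESeq2 6. The 2 past the threshold over all genes were Bnip3, a mitophagy receptor (24.1 ± 3.92 to 61.5 ± 14.9 CPM), and Egln3, a prolyl hydroxylase acting on HIF (18.6 ± 3.04 to 40.8 ± 7.34 CPM). Examples adjusted over the list alone were Pdk1, whose product inhibits pyruvate dehydrogenase (log2 fold change 0.72; 143 ± 20.8 to 235 ± 30.3 CPM), and the phosphofructokinase gene Pfkl (0.61; 361 ± 15.6 to 554 ± 44.2 CPM). The list's median was 0.49 within the 4 libraries and 0.37 in dKO clone 3 against control clone 1.

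**Figure D4:**
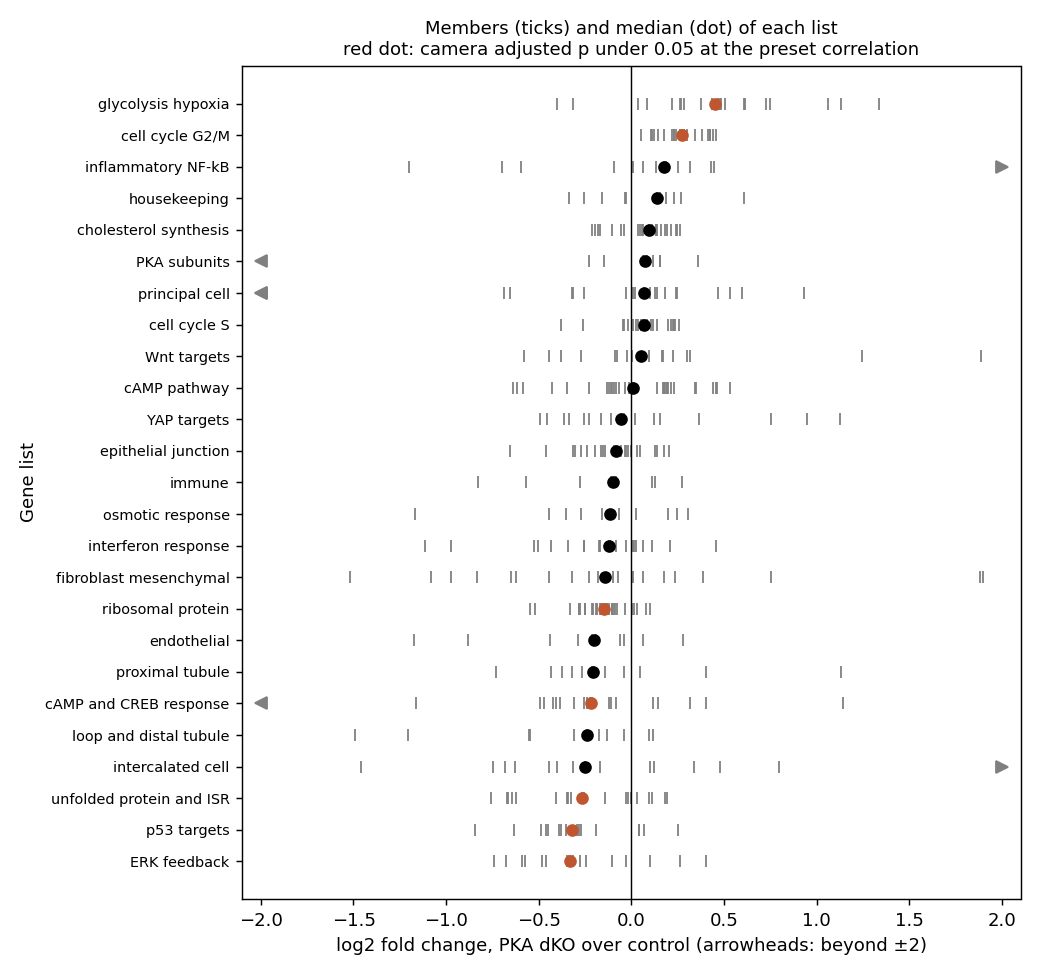
Log2 fold change of PKA dKO over control clones (horizontal axis) for the members (ticks, arrowheads beyond the axis) and the median (dot) of each of 25 gene lists. Red dots mark the 7 lists past the threshold with camera at the preset correlation, from a median of 0.45 for glycolysis and hypoxia to -0.33 for ERK feedback; none passed with an estimated correlation.

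Mitotic genes also rose as a list (median 0.27; camera adjusted p = 2.90e-07, adjusted p = 0.759 with an estimated correlation). All 24 members had a positive fold change, none passed over all genes or adjusted over the list alone, and 6 had an unadjusted p under 0.05; edgeR's quasi-likelihood test and DESeq2 also called none. Top2a, a topoisomerase of dividing cells, had 569 ± 38.6 CPM in control and 768 ± 96.7 CPM in dKO clones, and the checkpoint kinase gene Bub1 had 63.1 ± 8.47 and 84.2 ± 3.24 CPM. The 22 S-phase genes did not pass as a list (camera adjusted p = 0.229), with Cdt1 at -0.38 and Cdc6 at 0.26.

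Genes that report ERK signalling and its feedback fell as a list (median -0.33; camera adjusted p = 9.72e-05, adjusted p = 0.286 with an estimated correlation). None of its 17 members passed over all genes, with limma or the quasi-likelihood test; 4 were lower adjusted over the list alone, 7 were lower and 1 higher at an unadjusted p under 0.05, and DESeq2 called 2 lower. The 4 were the ERK phosphatase gene Dusp6 (146 ± 14.7 to 97.9 ± 7.65 CPM), the feedback inhibitor genes Spry1 (log2 fold change -0.46) and Spry2 (-0.68), and Fosl1 (-0.59). Spry2 lies on chromosome 14, whose genes had a median deviation of -0.42 in dKO clone 3 and 0.29 in control clone 1; with chromosome medians removed the list still passed (adjusted p = 2.08e-04). The list did not pass within the 4 libraries (adjusted p = 0.118), and over 14 alternatives its adjusted p ran from 4.91e-05 to 0.286.

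Targets of cyclic AMP and CREB fell as a list (median -0.22; camera adjusted p = 1.13e-03, adjusted p = 0.295 with an estimated correlation). Pde4b alone of 23 members passed, over all genes and adjusted over the list alone. The growth factor gene Areg had 6.84 ± 3.96 and 2.84 ± 0.90 CPM (log2 fold change -1.16) and Bdnf -0.47, while the coactivator gene Ppargc1a stood at 1.14, none of them past the threshold. This list did not pass without control clone 1 (adjusted p = 0.150) or within the 4 libraries (0.0530), with a range of 1.05e-04 to 0.295 over 14 alternatives. Pde4b, which degrades cyclic AMP, was placed in that list of targets. It was not among 32 other genes of cyclic AMP synthesis, breakdown and anchoring. None of these 32 genes passed with limma, the quasi-likelihood test or DESeq2. Of them, 3 had an unadjusted p under 0.05, and their list did not pass (camera adjusted p = 0.634). They included the adenylyl cyclase gene Adcy6 (-0.23), the anchoring protein gene Akap13 (-0.35), the phosphodiesterase gene Pde4c (0.45) and Pde5a (0.53), whose product acts on cyclic GMP rather than cyclic AMP.

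Ribosomal protein genes fell by a small amount as a list (median -0.15; camera adjusted p = 1.88e-05, adjusted p = 0.759 with an estimated correlation). Of 33 members 28 had a negative fold change and none passed with limma, over all genes or adjusted over the list alone, or with the quasi-likelihood test; 2 had an unadjusted p under 0.05 and DESeq2 called 2. Those with the lowest p were Rpl37 (-0.52) and Rpl30 (-0.55), both on chromosome 15. Genes of the unfolded protein and integrated stress responses fell as a list (median -0.26; camera adjusted p = 8.84e-03, adjusted p = 0.759 with an estimated correlation), and the asparagine synthetase gene Asns (log2 fold change -0.64; 212 ± 46.9 to 133 ± 2.17 CPM) was lower adjusted over the list alone; this list was no longer called without control clone 3 (0.0893), dKO clone 1 (0.0852) or dKO clone 2 (0.186), in a range of 1.35e-05 to 0.759 over 14 alternatives. Targets of p53 fell as a list (median -0.32; camera adjusted p = 0.0152, adjusted p = 0.759 with an estimated correlation) with none of 16 members past the threshold, for example Phlda3 (-0.64) and Mdm2 (-0.29); 1 had an unadjusted p under 0.05, and neither the quasi-likelihood test nor DESeq2 called any. That list turned upward, past no threshold, without control clone 1 (adjusted p = 0.941) and within the 4 libraries (0.775), and was lost without dKO clone 2 (0.135) and with the split of libraries as a term (0.0517); the lowest adjusted p over its alternatives was 6.12e-07, without control clone 2.

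The remaining 18 lists did not pass camera in the main setting. In at least 1 of 14 alternatives, lists of loop and distal tubule, junction, interferon, osmotic, cholesterol, S-phase and housekeeping genes passed. Rhcg was the only 1 of 15 intercalated-cell genes past the threshold; the carbonic anhydrase gene Car2 stood at -0.44 (169 ± 16.3 to 127 ± 37.5 CPM), and the list had a median of -0.25, a mean of 0.08 and an adjusted p of 0.458. Lrp2 was the only 1 of 12 proximal-tubule genes past it (list adjusted p = 0.892, median -0.21). Of 11 genes of the loop of Henle and distal tubule none passed with limma, the quasi-likelihood test or DESeq2 and 2 had an unadjusted p under 0.05 (list adjusted p = 0.0906). Markers of other cell types did not pass as lists, at camera adjusted p = 0.629 for 20 fibroblast and mesenchymal genes, 0.629 for 10 endothelial genes and 0.462 for 8 immune genes, and limma, the quasi-likelihood test and DESeq2 called none of their members. At an unadjusted p under 0.05 there were 2 fibroblast and mesenchymal genes, both higher, and 1 immune gene, lower. Sparc had 7.09 ± 5.94 CPM in control and 23.1 ± 10.5 CPM in dKO clones, Twist1 had a log2 fold change of 1.88 (SE 0.62), and the monocyte gene Cd14 had 31.0 ± 8.78 and 20.7 ± 4.24 CPM.

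Epithelial and junction genes had a list adjusted p of 0.0632, with 4 of 23 members lower at an unadjusted p under 0.05, none past the threshold with limma or the quasi-likelihood test and 1 with DESeq2; the claudin gene Cldn8 had 335 ± 86.8 and 207 ± 12.8 CPM and Muc1 252 ± 26.5 and 183 ± 16.2 CPM. Interferon response genes had 0.0632, with Oas1a at -0.97 and Ifit2 at 0.46. Over 14 alternatives the list adjusted p ran from 2.55e-04 to 0.797 for interferon response genes. For epithelial and junction genes it ran from 5.95e-04 to 0.941. Osmotic response genes had 0.182, and of its 10 members Akr1b3, the aldose reductase gene, was lower adjusted over the list alone (130 ± 46.8 to 55.9 ± 11.9 CPM; log2 fold change -1.17). Wnt targets had 0.372, with Wnt9b (1.89) and Rnf43 (1.24) higher adjusted over the list alone, and YAP targets 0.936, with Ankrd1 (1.13), Cyr61 (0.75) and Tgfb2 (0.95) higher on that basis. Cholesterol synthesis had 0.229, inflammatory and NF-kB genes 0.240, and housekeeping genes 0.344, where the glycolytic gene Pgk1 (89.9 ± 12.6 to 136 ± 7.58 CPM) was higher adjusted over the list alone and Gapdh stood at 0.27. No transcript of the mitochondrial genome was in the table, so that list had 0 members.

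The authors' deposited table of their edgeR comparison listed 10190 transcripts, 354 of them at a false discovery rate under 0.05, with 100 higher and 254 lower in dKO clones. All 28 genes were among the 354 in the authors' deposited table, with the same direction. All 354 had the same sign of fold change in the limma fit, and across the 10190 genes, which are not independent replicates, the correlation of the 2 sets of log2 fold changes was 0.989. Both comparisons rest on the same 6 libraries, so the shared directions and this correlation are no independent check of the 28 genes. For Prkaca and Aqp2 the authors' deposited table gave log2 fold changes of -3.73 and -6.41.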

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

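The settings added after the data were seen were the quasi-likelihood test, the term, covariate and subset for the 2 libraries that stood apart, the pseudocounts of 0.25 and 4, the removal of chromosome medians and the exact test on the authors' transcripts. Over 26 settings none of the 28 genes changed sign, which groups that do not overlap leave little room for. In all of them 8 stayed past the threshold: Prkaca, Aqp2, Pde4b, Gsdmc2, Ggt1, Hid1, Upk1a and AU021092. The setting with a threshold of 0.01 left only these 8, so it alone set the highest count possible. Gsdmc4 and Zhx2 also kept an adjusted p under 0.05 in every setting (highest 0.0431 and 0.0434). Of 598 values of the 23 named genes past the threshold, 92 lost the call, including those lost only to the threshold of 0.01. Of the other named genes, 130 values gained it. Prkaca passed in all 26 settings and Prkacb in none. Small changes can be missed, since 1.5-fold changes were recovered for 7.46% of simulated genes with a mean above 1 CPM. Lower genes were not checked, and how far depth sets this was not tested.

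The count of 28 genes (9 higher, 19 lower) moved by over 1.5 times in these settings, and the cause was not tested except where given. DESeq2 called 213 (61 higher, 152 lower), with 4208 adjusted p-values not given, edgeR's exact test 154 (41, 113), and the exact test on the authors' transcripts, which tests fewer genes, 370 (110, 260). FPKM with a pseudocount of 1 gave 123 (38, 85) and with 0.1 91 (25, 66). A threshold of 0.01, stricter by construction, left 8 (1 higher, 7 lower). The term for the 2 libraries gave 71 (20, 51), the covariate 55 (14, 41) and the other 4 libraries alone 525 (270, 255). Leaving out 1 library gave 11 to 146 genes, 2 to 81 higher and 9 to 65 lower, with the lowest count without dKO clone 2 and the highest without control clone 1; 8 of the 28 calls were lost without control clone 2, 8 without control clone 3, 4 without dKO clone 3, 15 without dKO clone 1, 17 without dKO clone 2 and 0 without control clone 1. RLE, upper-quartile factors, no filter, the 1 CPM filter, limma-voom, the quasi-likelihood test, the other pseudocounts and removal of chromosome medians gave 22 to 32 genes.

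The labels do not pair the clones. The correlation of deviations from the group means was -0.357, 0.639 and -0.339 for clones of the same number, and control clones 1, 2 and 3 correlated best with dKO clones 3, 2 and 2. With the clone number as a replicate block 196 genes passed (60 higher, 136 lower), all 28 among them, and the same 7 lists passed.

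The number of lists fell from 7 to 0 with an estimated correlation and to 0 with fry, and was 6 to 10 in the other settings. Of the values of single lists, 22 lost the call with the same sign, 2 lost it with the sign reversed and 17 gained it. The p53 list reversed without control clone 1 (adjusted p = 0.941) and in the other 4 libraries (0.775), and leaving out 1 library gave 6.12e-07 to 0.941. The genes shared with the authors' table, 28, became 8 at a threshold of 0.01 in both, 138 with the exact test and 311 with the exact test on their transcripts. Reversed log2 fold changes, none past a threshold, belonged to 7 genes, with these ranges over the fits leaving out 1 library: Cd74 -0.24 to 0.75, Csf1r -0.16 to 0.38, Emcn -0.87 to 0.0024, Nfat5 -0.48 to 0.089, Scnn1a -0.14 to 0.14, Scnn1b -0.39 to 0.39 and Scnn1g -0.074 to 0.39. Within those ranges Scnn1a was also -0.035 without dKO clone 1 and Scnn1b -0.092 without control clone 2. In the other 4 libraries Cd74 was -0.34 and Csf1r -0.28. Scnn1a was -0.0023 with DESeq2 and -0.014 with the exact test on the authors' transcripts, and Scnn1b -0.0035 with the 1 CPM filter. The cause was not tested for the reversals or for the moved counts of lists. The count of shared genes rose with the test used and with the transcripts tested. With the exact test on the authors' transcripts 370 genes passed, 311 of them among the authors' 354. The 2 sets of log2 fold changes then correlated at 0.99999 across genes, which are not independent replicates.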

Other observations

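Tests chosen only after the result was seen were those of other splits for the gene count, of depth and genotype for the 2 libraries that stood apart, and of a whole-chromosome shift for chromosome 15.

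Uroplakin and gasdermin C genes among the 28 led to a list of urothelial genes, made after the data were seen. Of its 18 genes tested, Upk1a, Upk3b, Gsdmc2 and Gsdmc4 passed the threshold. Upk2 (2.76 ± 0.34 to 1.17 ± 0.14 CPM) and Klf5 (68.9 ± 8.66 to 40.7 ± 5.24 CPM) had lower means without passing, and the keratin gene Krt20 had 214 ± 13.7 and 214 ± 4.78 CPM. The hypothesis of a wider lower level of urothelial genes was tested on the 14 others, whose median log2 fold change was -0.13. Camera gave p = 1.84e-03 at the preset correlation used to call the fixed lists, and p = 0.158 with an estimated correlation. This hypothesis stays open. Some glutathione transferase and related genes lay near the threshold, such as Gstt2 (16.9 ± 1.94 to 8.16 ± 0.55 CPM, limma adjusted p = 0.0609) and Akr1c19 (51.9 ± 5.05 to 29.4 ± 2.06 CPM, 0.0512). Others lay far from it, such as Gsta3 (limma adjusted p = 0.679) and Gstt1 (0.929). In a list of 28 xenobiotic response genes, also made after the data were seen, 0 passed the threshold. The 21 left after removing those with the lowest p had a median of -0.27. For them camera gave p = 1.19e-03 at the preset correlation and p = 0.0864 with an estimated correlation, which leaves a wider change open too. Gstm1, at 555 ± 53.8 and 556 ± 78.6 CPM, differed by less than the spread between clones.

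The real grouping of the 6 libraries gave 28 genes and the highest of the other splits 1. Only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.

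Control clone 1 and dKO clone 3 had fewer detected transcripts and fewer receptor reads, at 0.041 and 0.042 RPKM computed from recovered reads against 0.134 to 0.237 in the other 4 libraries. The tables argue against depth of recovered reads as the cause, because 2 of the other 4 libraries have fewer than both. Control clone 1 and dKO clone 3 had, however, the 2 smallest library totals implied by the FPKM values. Depth on that measure therefore stays open. Reads in the table were 48.7% and 48.1% of those totals, against 31.7% to 39.9% in the other 4 libraries. Genotype is excluded as the sole cause, since the 2 libraries belong to 2 groups. Background reads spread evenly over the genome may be a candidate source in the other 4 libraries. Their lower share of reads in the table goes with this source without singling it out. Receptor reads rose only weakly with transcript length (lowest Spearman rho 0.252 across transcripts, which are not independent). The receptor families also differed up to 1.94 times in rate, so background reads cannot be told apart from other sources with these tables.

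In dKO clone 3 the genes of chromosomes 6 and 14 had median deviations of -0.38 and -0.42 from the median over libraries. A few strongly changed genes would not give this, as at least 96.7% of the genes on each chromosome lay below the library's median. Background reads are argued against by a shift of the more abundant genes at 0.987 times that of the others or more. All 8 blocks of consecutive genes, 4 per chromosome, had a median below -0.2, consistent with fewer copies of these chromosomes in that clone, a hypothesis since no DNA was measured; smaller shifts were seen in control clone 1 (chromosome 14 at 0.29, 10 at -0.22, 12 at -0.24) and control clone 2 (chromosome 8, which holds Prkaca, at -0.20). Chromosome 15 held 8 of the 28 genes, all lower, against 1.18 expected from its share of the genes tested (two-sided Fisher's exact test, p = 1.39e-05, adjusted p = 2.91e-04 over 21 chromosomes, where genes are not independent). Its medians averaged -0.07 in dKO and 0.04 in control clones, and each dKO median (-0.10 to -0.05) lay below each control median (-0.01 to 0.09). The log2 fold changes of the 8 genes ran from -6.30 to -0.85, far beyond a shift of this size. This argues against a shift of the whole chromosome as their cause. After each library's chromosome medians were removed 7 of the 8 calls stayed, but so small a step could end few calls. A shift of part of the chromosome was not tested.

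The glycolysis and hypoxia list had a median of 0.45. This median stood at percentile 100 of 10000 random lists matched on expression (central range -0.09 to 0.12). Lists of like expression thus did not shift as far. The lists were matched on expression alone, so background differences acting through other gene features, such as transcript length, could give the same percentile. Random lists also leave out the correlation among the list's own genes. Background differences therefore stay open. A single library does not carry the higher median of the list, since the lowest median with 1 library left out was 0.363. The real split had the median farthest from 0, in 1 of 10 splits, with 0.244 the highest of the others, and 10 splits are too few for a share under 0.05. A metabolic difference that goes with the PKA dKO label is a hypothesis that stays open beside clonal or culture differences, such as cell density or oxygen at harvest, which were not tested.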
